A study of Homo sapiens with 18 samples.

How the data were processed

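RNA-seq of cultured human epidermal keratinocytes was analysed, 18 libraries in 6 groups of 3 (PBS, TWEAK, TNF, IL-17A, TWEAK with TNF, and TWEAK with IL-17A). Total RNA was extracted with Trizol and sequenced as paired ends on a NovaSeq, per the labels' protocols. Raw counts per gene were deposited. The submitters' processing notes name Bowtie 1.0.0, STAR 2.6.1 and featureCounts 1.6.5 and the genome GRCh38, without the role of each, the annotation, the strandedness or the handling of reads shared between genes. The count table names 38500 genes, of which 36323 match a GENCODE 29 identifier with its version and 38351 without it. Depth was 27.0 to 37.8 M counts per library, so 3 counts over a group, the floor used for genes without counts, stand for 0.0255 to 0.0385 CPM.

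Counts were tested in R 4.3.3 with edgeR 4.0.16: TMM scaling, filterByExpr on the 6 groups, and the robust quasi-likelihood F test on 1 model of 6 group means. Of the genes in the table, 120 sex-linked ones were left out of tests, and 17598 passed the filter. The 13 comparisons were each treatment against PBS, each combination against each of its parts, TWEAK against TNF and against IL-17A, and the 2 interactions. P-values were adjusted by Benjamini-Hochberg within a comparison, with a threshold of 0.05. CPM values were computed from the counts with the TMM-scaled library sizes. The SE of a log2 fold change was derived from the F statistic, and the median prior degrees of freedom were 19.37.

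The comparisons, tests, 27 gene lists and most alternatives were set before the data were examined. The lists are CXCR2-ligand chemokines, other chemokines, IL-1 and IL-36 family, other cytokines and growth factors, antimicrobial proteins and alarmins, NF-kB feedback and target genes, interferon-stimulated genes, antigen presentation, receptors and ligands of the stimuli, hyperproliferation keratins, suprabasal differentiation, small proline-rich and LCE3 proteins, basal layer and hemidesmosome, epidermal serpins, matrix remodelling and wound edge, cell cycle, cholesterol synthesis, hypoxia and glycolysis, complement, p53 targets, unfolded protein and integrated stress response, heat shock, melanocyte markers, fibroblast markers, leukocyte and Langerhans cell markers, endothelial markers and mitochondrially encoded genes, and 9 of their symbols were not in the table. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01 and, as alternatives, with an estimated correlation and with fry. Genes are named by a rule: the 10 largest rises and falls against PBS, and 6 for the other comparisons and interactions, past the threshold, with a mean log2 CPM of at least 1 and libraries that do not overlap between the groups (interactions without this last condition), shortened to the first members where space required. Some genes the rule names are left out. For lists described, up to 4 called members with the largest change are named, or 2 of the highest level if none was called. The 20 genes fixed in advance are given whatever the result, except IL17C (not analysed) and, in some comparisons, DEFB4A.

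Alternatives were RLE size factors, upper-quartile scaling, no filter, a stricter filter (1 CPM in 3 libraries and 100 counts in all), DESeq2 1.42.0, limma-voom, a fit of only the groups compared, the replicate number in the model, a fold threshold of 1.5 in the test, an adjusted p under 0.01, and each library left out in turn. Shared controls were modelled by 20 simulations without effect. The tests were tried on simulated data with 200 changed genes, not split by level. In a layout like TWEAK against PBS, 88.8% of genes changed 1.5-fold, 93.8% changed 2-fold and 100% changed 4-fold were called, with 13 false calls (6.5% of calls). In a TNF interaction the shares were 62.5%, 85% and 100%, with 4 false calls (2.5%). Camera called 0 of 26 random lists, which lack the correlation of real lists. Replicate counts were checked for a repeated library, and chi-square per degree of freedom (2.331 or more) showed none.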

Results

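Gene expression was measured by paired-end sequencing of total RNA from cultured human epidermal keratinocytes, the main cell type of the outer layer of skin. Cells received PBS, TWEAK at 100 ng/ml, TNF at 10 ng/ml, IL-17A at 100 ng/ml, TWEAK with TNF, or TWEAK with IL-17A, for 48 h. TWEAK is a cytokine of the TNF superfamily, encoded by TNFSF12, and its receptor on keratinocytes is encoded by TNFRSF12A. TNF and IL-17A are inflammatory cytokines whose blockade is used to treat psoriasis. Each of the 6 groups had 3 libraries, 18 in all. Total counts per library, in M, were 35.1, 35.5 and 37.8 for PBS, 31.1, 28.2 and 34.9 for TWEAK, 29.2, 31.9 and 29.8 for TNF, 33.9, 37.0 and 28.7 for IL-17A, 28.7, 27.0 and 32.7 for TWEAK with TNF, and 28.9, 34.0 and 34.8 for TWEAK with IL-17A. Between 24705 and 27393 genes per library had at least 1 count. On the 2000 most variable genes, the first principal component held 62.8% of the variance and the second 14.7%, and the 3 libraries of each group lay together. Mitochondrially encoded genes took 1.94% ± 0.03 of the counts in PBS, 1.07% ± 0.03 in TNF and 1.14% ± 0.04 in TWEAK with TNF (mean ± SD, n = 3). The labels describe triplicate wells and name no donors, so p-values measure only the spread between these libraries. A library is named by its group and replicate number. Levels are given in CPM, counts scaled to library size, as mean ± SD with n = 3, and changes as folds, with the log2 fold change ± SE in brackets, or as log2 fold changes ± SE, with 3 libraries in each group. Lists of genes, cut to the members tested, were tested with camera. An adjusted p with an estimated correlation follows where that ends the call of a list. Levels are relative to all counted RNA, and the scaling assumes that most genes did not change, while 59.6% of the tested genes passed the test with TNF.

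Of 17598 genes tested, 5429 changed with TWEAK against PBS, 10485 with TNF and 6408 with IL-17A, by edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p under 0.05. More than 2-fold, 438 genes rose and 225 fell with TWEAK, 1335 rose and 1866 fell with TNF, and 575 rose and 373 fell with IL-17A. TWEAK with TNF changed 11295 genes against PBS, and TWEAK with IL-17A changed 7849.

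**Figure D1:**
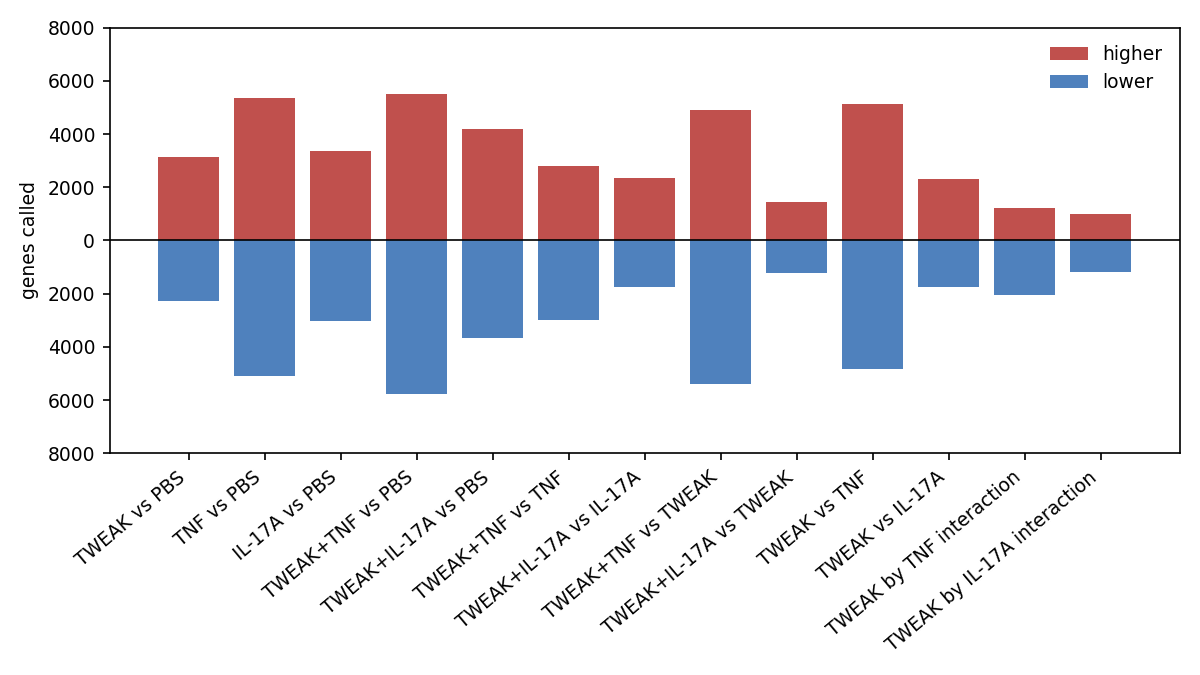
Bars give the number of genes that rose (above 0) or fell (below 0) in each of the 13 comparisons, by edgeR's quasi-likelihood test at an adjusted p under 0.05. The comparison of TWEAK with TNF against PBS has the most, with 11295, and the interaction of TWEAK with IL-17A the fewest, with 2193.

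The comparison of TWEAK with PBS asks what TWEAK alone does to keratinocytes. MMP9, a gelatinase that degrades basement membrane, stood at 4.82 ± 0.552 CPM in PBS and 1003 ± 97.4 CPM in TWEAK, a 208-fold rise (log2 fold change 7.70 ± 0.17). The neutrophil-attracting chemokine CXCL5 rose 31.1-fold (4.96 ± 0.48), the acute-phase protein SAA1 27.3-fold (4.77 ± 0.29), and IL23A, which encodes the subunit specific to IL-23, 16.5-fold (4.04 ± 0.13). The hydroxycarboxylic acid receptors HCAR3 and HCAR2 rose 18.8-fold and 14.2-fold, VNN1, a pantetheinase near the floor in PBS, 17.7-fold (4.15 ± 0.53), the phospholipase PLA2G4C 13.7-fold (3.78 ± 0.12), and the apoptosis inhibitor BIRC3 13.1-fold (3.71 ± 0.16). HCAR2 and HCAR3 are near-identical, and how shared reads were counted is not stated. ZP4, a zona pellucida gene of the oocyte coat, had 364 counts over the TWEAK libraries and 1 over the PBS libraries, a ratio of 441 (95% counting interval 78.6 to 17450). Such intervals, and the floor of 3 counts used below, cover counting error only. Among the falls, ITGA4, an integrin chain, had a log2 fold change of -2.19 ± 0.14, followed by CNNM1 (-1.97 ± 0.17), CXCL14 (-1.94 ± 0.11), TP73 (-1.93 ± 0.16) and DMBT1 (-1.84 ± 0.29). CXCL14 encodes a chemokine of resting epidermis and TP73 a transcription factor of the p53 family.

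NF-kB feedback and target genes rose as a group with TWEAK: of 18 members, 13 rose, 0 fell and 5 did not pass (adjusted over the list alone, 14 and 1, camera higher, adjusted p = 1.02e-31). NFKB2, the precursor of the non-canonical pathway subunit, rose 5.66-fold, NFKBIE 3.75-fold and the adhesion molecule ICAM1 4.07-fold. Of 6 CXCR2-ligand chemokines, which attract neutrophils, 4 rose, 0 fell and 2 did not pass (adjusted over the list alone, 4 and 0, camera higher, adjusted p = 1.31e-05). CXCL3 rose 9.28-fold, CXCL1 2.76-fold and CXCL2 2.36-fold. Among 5 other chemokines, 1 rose, 1 fell and 3 did not pass (adjusted over the list alone, 2 and 1, camera higher, adjusted p = 0.464). CXCL16 rose 2.52-fold. The IL-1 and IL-36 family had 11 members, of which 5 rose, 1 fell and 5 did not pass (adjusted over the list alone, 5 and 1, camera higher, adjusted p = 0.00385), among them the decoy receptor IL1R2 (2.71-fold) and IL1B (1.81-fold). Other cytokines and growth factors numbered 16, and 8 rose, 1 fell and 7 did not pass (adjusted over the list alone, 8 and 1, camera higher, adjusted p = 4.93e-11). IL32 rose 13.0-fold and the granulocyte growth factor CSF3 5.11-fold. In contrast, of 11 antimicrobial proteins and alarmins, 2 rose, 1 fell and 8 did not pass (adjusted over the list alone, 2 and 1, camera higher, adjusted p = 0.681). LCN2, an iron-sequestering antibacterial protein, fell with a log2 fold change of -0.37 ± 0.06 while the elastase inhibitor PI3 rose 1.71-fold. With TWEAK, leaving out 1 library moved the log2 fold changes of CXCL3 (without PBS 1, 3.88).

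Antigen presentation genes rose, 4.29-fold for the immunoproteasome subunit PSMB9, 3.49-fold for the invariant chain CD74 and 2.06-fold for HLA-B, and of 15 members, 12 rose, 0 fell and 3 did not pass (adjusted over the list alone, 14 and 0, camera higher, adjusted p = 7.34e-13). Of 30 interferon-stimulated genes, 19 rose, 2 fell and 9 did not pass (adjusted over the list alone, 20 and 2, camera higher, adjusted p = 1.53e-05, adjusted p = 0.285 with an estimated correlation), including XAF1 (4.21-fold), USP18 (2.47-fold) and the sensor IFIH1 (2.37-fold). Receptors and ligands of the stimuli had 11 members, and 9 rose, 0 fell and 2 did not pass (adjusted over the list alone, 9 and 0, camera higher, adjusted p = 1.31e-05), TNF itself at 3.54-fold, MAP3K14, the kinase NIK, at 1.92-fold and the TWEAK receptor gene TNFRSF12A at 1.15-fold. Of 16 cholesterol synthesis genes, 16 rose, 0 fell and 0 did not pass (adjusted over the list alone, 16 and 0, camera higher, adjusted p = 1.72e-14). The prenyl synthase FDPS rose 1.73-fold and HMGCS1 1.54-fold. Matrix remodelling and wound-edge genes, besides MMP9, included the stromelysin MMP10 at 3.95-fold and the urokinase receptor PLAUR at 2.69-fold, and of 16 members, 12 rose, 3 fell and 1 did not pass (adjusted over the list alone, 12 and 3, camera higher, adjusted p = 1.72e-14). Of 16 basal layer and hemidesmosome genes, 9 rose, 2 fell and 5 did not pass (adjusted over the list alone, 9 and 3, camera higher, adjusted p = 1.59e-06). Epidermal serpins counted 8 members, of which 4 rose, 2 fell and 2 did not pass (adjusted over the list alone, 4 and 2, camera higher, adjusted p = 1.32e-07). SERPINB1 rose 4.64-fold. Of 13 unfolded protein and integrated stress response genes, 7 rose, 3 fell and 3 did not pass (adjusted over the list alone, 7 and 3, camera higher, adjusted p = 1.78e-04, adjusted p = 0.168 with an estimated correlation), the chaperone HSPA5 rising 3.98-fold. With TWEAK, leaving out 1 library moved the log2 fold changes of XAF1 (without PBS 1, 2.77).

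Of 21 suprabasal differentiation genes, 2 rose, 4 fell and 15 did not pass (adjusted over the list alone, 2 and 4, camera lower, adjusted p = 0.154). Log2 fold changes were -1.45 ± 0.18 for LY6D and -0.49 ± 0.08 for KRT10. Small proline-rich and LCE3 proteins of the cornified envelope numbered 13, and 2 rose, 0 fell and 11 did not pass (adjusted over the list alone, 2 and 0, camera higher, adjusted p = 0.238). SPRR2A rose 2.33-fold. Of 5 hyperproliferation keratins, 2 rose, 1 fell and 2 did not pass (adjusted over the list alone, 2 and 1, camera higher, adjusted p = 0.350). KRT6A rose 1.55-fold. Cell cycle genes had 25 members, and 1 rose, 9 fell and 15 did not pass (adjusted over the list alone, 2 and 13, camera lower, adjusted p = 0.00251, adjusted p = 0.495 with an estimated correlation). With upper-quartile scaling 14 fell, PLK1 among the falls with a log2 fold change of -0.38 ± 0.07. Of 14 hypoxia and glycolysis genes, 2 rose, 7 fell and 5 did not pass (adjusted over the list alone, 2 and 9, camera lower, adjusted p = 2.85e-05, adjusted p = 0.217 with an estimated correlation). Log2 fold changes were -1.10 ± 0.13 for ADM and -0.65 ± 0.05 for SLC2A1. Among 10 complement genes, 2 rose, 2 fell and 6 did not pass (adjusted over the list alone, 2 and 2, camera higher, adjusted p = 0.195). Among 12 p53 targets, 3 rose, 5 fell and 4 did not pass (adjusted over the list alone, 3 and 6, camera lower, adjusted p = 0.350). Among 10 heat shock genes, 3 rose, 4 fell and 3 did not pass (adjusted over the list alone, 3 and 5, camera lower, adjusted p = 0.478). Of 13 mitochondrially encoded genes, 0 rose, 3 fell and 10 did not pass (adjusted over the list alone, 0 and 2, camera lower, adjusted p = 0.153), and 7 fell with upper-quartile scaling.

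Of 5 melanocyte markers, 0 rose, 2 fell and 3 did not pass (adjusted over the list alone, 0 and 2, camera lower, adjusted p = 0.195), with log2 values of -3.43 ± 0.59 for KIT (6 counts against 83) and -1.08 ± 0.21 for MITF. Of 6 fibroblast markers, 0 rose, 1 fell and 5 did not pass (adjusted over the list alone, 0 and 1, camera lower, adjusted p = 0.350), FBLN1 falling with a log2 fold change of -0.32 ± 0.06. Of 4 leukocyte and Langerhans cell markers, 2 rose, 0 fell and 2 did not pass (adjusted over the list alone, 2 and 1, camera higher, adjusted p = 0.350). ITGAM rose 8.60-fold. The 1 endothelial marker measured, TEK, had a log2 fold change of -0.50 ± 0.54 and did not pass (adjusted over the list alone, 0 and 0, camera lower, adjusted p = 0.701). In the other comparisons with PBS, in the order TNF, IL-17A, TWEAK with TNF and TWEAK with IL-17A, 1, 0, 0 and 0 of 5 melanocyte markers rose and 2, 3, 2 and 3 fell, 1, 1, 3 and 1 of 6 fibroblast markers rose and 3, 2, 2 and 2 fell, and 2, 1, 2 and 2 of 4 leukocyte and Langerhans cell markers rose and 0, 1, 1 and 1 fell. Of the 4 comparisons TEK passed only with TNF, at 1.57 ± 0.43. Median, mean and camera differed in sign for melanocyte markers with TNF, fibroblast markers with TNF, with TWEAK and TNF and with TWEAK and IL-17A, and leukocyte markers with IL-17A. The numbers were the same adjusted over the list alone, and camera called none of these lists (adjusted p = 0.0593 or more). Genes fixed in advance for naming that did not pass had log2 fold changes of 1.06 ± 0.43 for CCL20, -0.51 ± 0.53 for CXCL8, 0.54 ± 0.55 for IL36G and 0.40 ± 0.24 for TSLP. S100A7 did not pass either, at 0.40 ± 0.52, nor did S100A8 at 0.85 ± 0.35, KRT16 at -0.03 ± 0.19, FLG at -0.39 ± 0.15 and MKI67 at -0.25 ± 0.13. DEFB4A had 0 counts in both groups, which allows up to 3 counts over either group. With TWEAK, leaving out 1 library brought a call for FLG (without PBS 1, adjusted p = 0.00140). With the replicate number in the model, S100A8 (adjusted p = 0.0419) and FLG (adjusted p = 0.0176) passed. With TNF, leaving out 1 library ended the call of TEK (without TNF 1, adjusted p = 0.0956, log2 fold change 0.93).

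**Figure D2:**
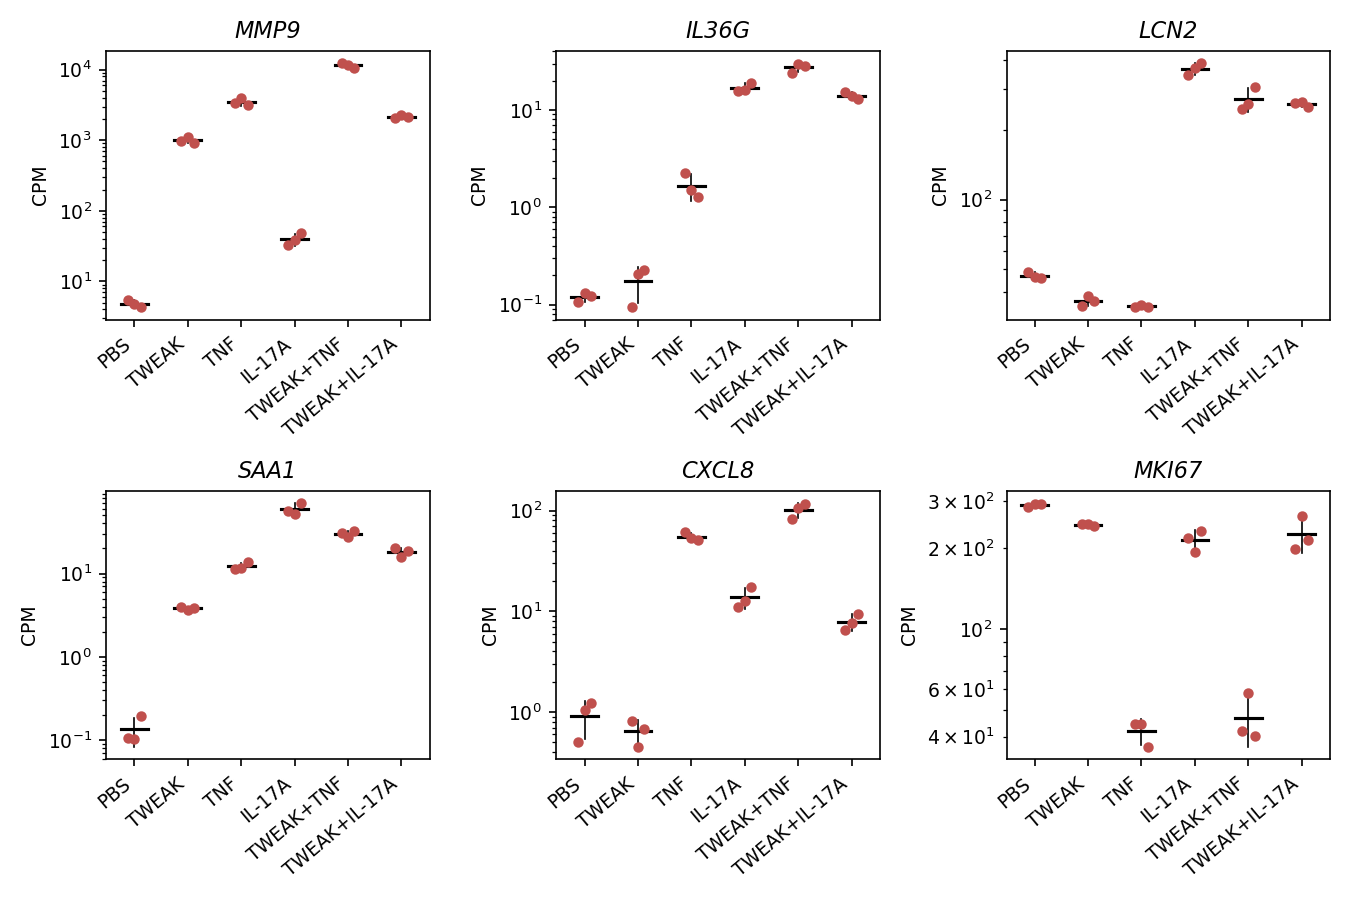
Each point is the level of 1 gene in 1 library, in CPM on a log axis, for MMP9, IL36G, LCN2, SAA1, CXCL8 and MKI67 in the 6 groups, with the mean as a line and the SD as a bar (n = 3).

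The comparison of TNF with PBS gives the response to a classical inflammatory cytokine for reference. CXCL5 rose 748-fold (9.55 ± 0.31) and MMP9 718-fold, to 3461 ± 399 CPM. The central complement component C3 rose 382-fold (8.58 ± 0.44), from 0.186 ± 0.165 to 73.0 ± 6.87 CPM, the cytokine IL32 286-fold (8.16 ± 0.17), the adhesion molecule ICAM1 152-fold (7.25 ± 0.15) and the protease CTSS 147-fold (7.20 ± 0.18). SAA1 and the endothelial-cell-specific molecule gene ESM1 rose 87.6-fold and 85.2-fold. Ratios of counts were 981 (95% counting interval 176 to 38790) for ZP4 (703 counts against 1) and 149.7 (95% counting interval 50.8 to 729.9) for C15orf48 (322 against 3). By the naming rule, the leading falls had log2 fold changes of -5.94 ± 0.17 for METTL7A, -5.43 ± 0.21 for ITGA4, -5.08 ± 0.23 for TP73, -4.63 ± 0.18 for PADI3 and -4.31 ± 0.25 for ANK1, PADI3 being a deiminase of the upper epidermis and ANK1 an ankyrin. With TNF, leaving out 1 library moved the log2 fold changes of TP73 (without TNF 3, -5.79).

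Each of the 25 cell cycle genes measured fell with TNF: 0 rose, 25 fell and 0 did not pass (adjusted over the list alone, 0 and 25, camera lower, adjusted p = 1.17e-54). Log2 fold changes were -3.25 ± 0.07 for the mitotic activator CDC20, -3.23 ± 0.07 for the survivin gene BIRC5, -3.20 ± 0.14 for the topoisomerase TOP2A and -2.80 ± 0.14 for the proliferation marker MKI67. Mitochondrially encoded genes moved in the same libraries: of 13, 0 rose, 13 fell and 0 did not pass (adjusted over the list alone, 0 and 13, camera lower, adjusted p = 1.94e-08, adjusted p = 0.0761 with an estimated correlation), and their share of the counts was 1.07% ± 0.03 against 1.94% ± 0.03 in PBS. Of 18 NF-kB feedback and target genes, 18 rose, 0 fell and 0 did not pass (adjusted over the list alone, 18 and 0, camera higher, adjusted p = 3.64e-40), including BIRC3 (19.1-fold), TNFAIP2 (18.2-fold) and the mitochondrial dismutase SOD2 (16.3-fold). Of 11 members of the IL-1 and IL-36 family, 9 rose, 2 fell and 0 did not pass (adjusted over the list alone, 9 and 2, camera higher, adjusted p = 1.97e-15). IL1R2 rose 43.0-fold, IL36G 13.6-fold and IL1RN 10.2-fold. CXCR2-ligand chemokines had CXCL8 at 59.2-fold and CXCL3 at 42.4-fold, and of 6, 5 rose, 0 fell and 1 did not pass (adjusted over the list alone, 5 and 0, camera higher, adjusted p = 2.80e-12). Of 16 other cytokines and growth factors, 12 rose, 2 fell and 2 did not pass (adjusted over the list alone, 12 and 2, camera higher, adjusted p = 2.66e-12). CSF2 rose 43.1-fold and IL6 18.1-fold. Antigen presentation genes numbered 15, and 15 rose, 0 fell and 0 did not pass (adjusted over the list alone, 15 and 0, camera higher, adjusted p = 3.82e-16). CD74 rose 8.07-fold. With TNF, leaving out 1 library moved the log2 fold changes of CXCL3 (without PBS 1, 6.07) and IL6 (without PBS 2 and 3, 4.96 and 3.58).

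Of 11 antimicrobial proteins and alarmins with TNF, 7 rose, 1 fell and 3 did not pass (adjusted over the list alone, 7 and 1, camera higher, adjusted p = 0.00978, adjusted p = 0.415 with an estimated correlation). PI3 rose 8.64-fold, S100A9 5.41-fold and S100A8 4.74-fold, while LCN2 fell with a log2 fold change of -0.44 ± 0.07. Suprabasal differentiation genes split: of 21, 3 rose, 9 fell and 9 did not pass (adjusted over the list alone, 3 and 9, camera lower, adjusted p = 0.373). Log2 fold changes were -2.71 ± 0.73 for DSC1, -2.08 ± 0.45 for KRT1 and -1.16 ± 0.16 for FLG, the filaggrin gene. Of 16 matrix remodelling and wound-edge genes, 11 rose, 4 fell and 1 did not pass (adjusted over the list alone, 11 and 4, camera higher, adjusted p = 6.90e-12). MMP10 rose 19.0-fold and the collagenase MMP1 15.2-fold. Of 30 interferon-stimulated genes, 21 rose, 4 fell and 5 did not pass (adjusted over the list alone, 21 and 4, camera higher, adjusted p = 0.00155, adjusted p = 0.415 with an estimated correlation). RSAD2 rose 4.63-fold. Hypoxia and glycolysis genes had a median log2 fold change of 0.04 and a mean of -0.30, and the median was -0.03 with upper-quartile scaling, and of 14, 2 rose, 5 fell and 7 did not pass (adjusted over the list alone, 2 and 5, camera lower, adjusted p = 0.303), with SLC2A1 at a log2 fold change of -0.94 ± 0.05. Other genes fixed in advance that passed had log2 fold changes of 3.68 ± 0.30 for CCL20, 4.00 ± 0.18 for CXCL1, 2.02 ± 0.06 for IL1B and 4.17 ± 0.13 for IL23A. CSF3 also passed, at 3.04 ± 0.37, as did S100A7 at 1.49 ± 0.46, TNFRSF12A at 0.56 ± 0.05 and KRT16 at -0.75 ± 0.20. Those that did not pass had log2 fold changes of -0.27 ± 0.27 for TSLP and 0.13 ± 0.08 for KRT10. DEFB4A had 2 counts over the TNF libraries and 0 over the PBS libraries, both under the floor of 3. With TNF, leaving out 1 library brought a call for KRT10 (without PBS 2, adjusted p = 0.0142). It moved the log2 fold changes of DSC1 (without TNF 2, -3.62), KRT1 (without TNF 2, -2.69) and S100A7 (without PBS 3, 2.39). With TNF, the call ended for KRT16 with a fit of only the groups compared (adjusted p = 0.0717).

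The comparison of IL-17A with PBS gives the response to the cytokine targeted in psoriasis. SAA1 rose 422-fold (8.72 ± 0.20), from 0.135 ± 0.0524 to 59.2 ± 10.0 CPM, C3 420.0-fold (8.71 ± 0.44), the membrane protein gene PDZK1IP1 402-fold (8.65 ± 0.17), SAA2 265-fold (8.05 ± 0.31) and CSF3 264-fold (8.05 ± 0.19). The epidermal cytokine IL36G rose 138-fold (7.10 ± 0.21) and the cornified envelope gene SPRR2A 74.4-fold (6.22 ± 0.17). SAA1 and SAA2, and the SPRR2 genes, are close copies as well. DEFB4A, the gene of a beta-defensin, had 262 counts in IL-17A and 0 in PBS, at least 96.9-fold higher against a floor of 3 counts over the group. C15orf48 had 245 counts against 3, a ratio of 90.6 (95% counting interval 30.6 to 442). The leading falls by the naming rule, as log2 fold changes, were ANK1 (-3.26 ± 0.21), CPA4 (-2.95 ± 0.10), EPHB6 (-2.76 ± 0.22), CCK (-2.42 ± 0.19) and CNNM1 (-2.37 ± 0.17). With IL-17A, leaving out 1 library moved the log2 fold changes of SAA2 (without PBS 2, 8.72).

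Antimicrobial proteins and alarmins rose as a group with IL-17A: of 11, 10 rose, 0 fell and 1 did not pass (adjusted over the list alone, 10 and 0, camera higher, adjusted p = 6.31e-32). S100A12 rose 67.4-fold, S100A8 40.6-fold, S100A7, psoriasin, 15.3-fold and LCN2 7.84-fold, to 368 ± 21.7 CPM. Of 6 CXCR2-ligand chemokines, 6 rose, 0 fell and 0 did not pass (adjusted over the list alone, 6 and 0, camera higher, adjusted p = 1.37e-31). CXCL1 rose 22.8-fold, CXCL6 18.2-fold and CXCL8 14.7-fold, and the T-cell attractant CCL20 rose 26.9-fold. Of 18 NF-kB feedback and target genes, 17 rose, 0 fell and 1 did not pass (adjusted over the list alone, 17 and 0, camera higher, adjusted p = 9.17e-44), led by the ribonuclease gene ZC3H12A (10.6-fold) and NFKBIZ (8.93-fold), a nuclear regulator of IL-17 target genes. Interferon-stimulated genes numbered 30, and 27 rose, 1 fell and 2 did not pass (adjusted over the list alone, 27 and 1, camera higher, adjusted p = 9.17e-25). CMPK2 rose 6.49-fold and MX2 5.17-fold. Of 13 small proline-rich and LCE3 proteins, 10 rose, 0 fell and 3 did not pass (adjusted over the list alone, 10 and 0, camera higher, adjusted p = 3.69e-14). SPRR2D rose 16.4-fold. Other cytokines and growth factors had 16 members, of which 11 rose, 1 fell and 4 did not pass (adjusted over the list alone, 11 and 1, camera higher, adjusted p = 2.00e-20). IL23A rose 8.04-fold and IL6 9.52-fold. With IL-17A, leaving out 1 library moved the log2 fold changes of S100A7 (without PBS 3, 4.84), CXCL6 (without PBS 3, 5.48) and IL6 (without PBS 2 and 3, 4.03 and 2.66).

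Of 16 matrix remodelling and wound-edge genes with IL-17A, 13 rose, 1 fell and 2 did not pass (adjusted over the list alone, 13 and 3, camera higher, adjusted p = 1.41e-18). MMP10 rose 25.7-fold and MMP9 8.16-fold. Of 21 suprabasal differentiation genes, 3 rose, 12 fell and 6 did not pass (adjusted over the list alone, 3 and 12, camera lower, adjusted p = 0.148), the transglutaminase TGM1 rising 4.72-fold, against log2 fold changes of -1.92 ± 0.62 for DSC1, -1.81 ± 0.41 for KRT1 and -1.11 ± 0.16 for FLG. Of 25 cell cycle genes, 3 rose, 17 fell and 5 did not pass (adjusted over the list alone, 3 and 18, camera lower, adjusted p = 2.97e-04, adjusted p = 0.286 with an estimated correlation). CENPF had a log2 fold change of -1.05 ± 0.14. Other genes fixed in advance that passed with IL-17A had log2 fold changes of 1.78 ± 0.06 for IL1B, 2.04 ± 0.22 for ICAM1, -0.47 ± 0.08 for KRT10 and -0.43 ± 0.13 for MKI67. Among those that did not pass, log2 fold changes were 0.27 ± 0.24 for TSLP, 0.09 ± 0.05 for TNFRSF12A and -0.04 ± 0.19 for KRT16. With IL-17A, leaving out 1 library ended the calls of DSC1 (without PBS 3 and IL-17A 1 and 3, adjusted p = 0.0762 to 0.130) and MKI67 (without IL-17A 2, adjusted p = 0.0746). It moved the log2 fold changes of DSC1 (without IL-17A 2, -2.94). The call also ended for DSC1 with limma-voom and a fit of only the groups compared (adjusted p = 0.0554 to 0.0894).

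The combination of TWEAK with TNF was compared with PBS, with TNF and with TWEAK, to see what each cytokine adds to the other. Against PBS, CXCL5 rose 2682-fold (11.39 ± 0.30) and MMP9 2384-fold, MMP9 reaching 11490 ± 938 CPM. C3, ICAM1, CXCL3, CTSS, TNFAIP2 and MMP10 rose 1135-fold, 285-fold, 255-fold, 237-fold, 229-fold and 225-fold. Count ratios were 7082 (95% counting interval 1271 to 279800) for ZP4 and 1728 (95% counting interval 591 to 8381) for C15orf48, and DEFB4A, with 98 counts against 0, was at least 49.2-fold higher against the floor. Falls had log2 fold changes of -6.84 ± 0.25 for ITGA4, -6.32 ± 0.19 for METTL7A, -5.73 ± 0.21 for PADI3, -5.24 ± 0.23 for MYO3B and -4.83 ± 0.15 for CXCL14. Antimicrobial proteins and alarmins, with 11 members, now included LCN2 among the rises: 10 rose, 0 fell and 1 did not pass (adjusted over the list alone, 10 and 0, camera higher, adjusted p = 4.93e-08, adjusted p = 0.0662 with an estimated correlation). S100A8 rose 40.4-fold. Of 25 cell cycle genes, 0 rose, 25 fell and 0 did not pass (adjusted over the list alone, 0 and 25, camera lower, adjusted p = 1.67e-44). TOP2A had a log2 fold change of -3.47 ± 0.14. Mitochondrially encoded genes fell beside them: of 13, 0 rose, 13 fell and 0 did not pass (adjusted over the list alone, 0 and 13, camera lower, adjusted p = 1.76e-04, adjusted p = 0.206 with an estimated correlation). IL36G rose 223-fold. Other genes fixed in advance that passed in this comparison had log2 fold changes of 5.52 ± 0.25 for CCL20, 6.78 ± 0.26 for CXCL8, 5.93 ± 0.18 for CXCL1 and 2.52 ± 0.06 for IL1B. IL23A also passed, at 5.92 ± 0.12, as did CSF3 at 7.33 ± 0.20, S100A7 at 3.50 ± 0.36 and LCN2 at 2.54 ± 0.06. TNFRSF12A also passed, at 0.71 ± 0.05, as did KRT10 at -0.26 ± 0.09, FLG at -1.71 ± 0.17 and MKI67 at -2.64 ± 0.14. Genes of that set that did not pass had log2 fold changes of -0.38 ± 0.28 for TSLP and -0.06 ± 0.19 for KRT16. With upper-quartile scaling the median log2 fold change of all genes was -0.10, against -0.03 with the scaling used. In TWEAK with TNF against PBS, leaving out 1 library ended the calls of KRT10 (without PBS 2, adjusted p = 0.121). It moved the log2 fold changes of CXCL3 (without PBS 1, 8.65) and S100A7 (without PBS 3, 4.40).

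Against TNF alone, adding TWEAK raised SPRR2A 22.1-fold (4.47 ± 0.14), CSF3 19.6-fold (4.29 ± 0.15), IL36G 16.4-fold (4.04 ± 0.14), TNFAIP2 12.6-fold (3.65 ± 0.17), MMP10 11.8-fold (3.56 ± 0.13) and C15orf48 11.6-fold (3.53 ± 0.12). LCN2 rose 7.87-fold (2.98 ± 0.07), from 34.6 ± 0.315 to 272 ± 32.1 CPM, and of 5 other chemokines, 3 rose, 1 fell and 1 did not pass (adjusted over the list alone, 3 and 1, camera higher, adjusted p = 0.00141). CCL5 rose 24.2-fold. Falls had log2 fold changes of -2.51 ± 0.12 for the activin inhibitor FST, -2.39 ± 0.10 for ABI3BP and -2.18 ± 0.25 for the cystine transporter SLC7A11. In all, 2804 genes rose and 2995 fell, with 580 and 288 beyond 2-fold, while RLE size factors gave 3056 and 2648 and DESeq2 3032 and 2646. Of 11 antimicrobial proteins and alarmins, 9 rose, 1 fell and 1 did not pass (adjusted over the list alone, 9 and 1, camera higher, adjusted p = 2.44e-15). S100A8 rose 8.51-fold and S100A12 8.40-fold, and DEFB4A had 98 counts against 2, with a 95% counting interval of the ratio of 14.3 to 443. CXCR2-ligand chemokines numbered 6, and 6 rose, 0 fell and 0 did not pass (adjusted over the list alone, 6 and 0, camera higher, adjusted p = 5.05e-14). CXCL6 rose 9.52-fold. Of 18 NF-kB feedback and target genes, 16 rose, 0 fell and 2 did not pass (adjusted over the list alone, 16 and 0, camera higher, adjusted p = 5.04e-31). TRAF1 rose 6.75-fold. Small proline-rich and LCE3 proteins counted 13, of which 8 rose, 0 fell and 5 did not pass (adjusted over the list alone, 8 and 0, camera higher, adjusted p = 4.06e-09, adjusted p = 0.0859 with an estimated correlation). SPRR2E rose 7.97-fold. Of 16 matrix remodelling and wound-edge genes, 12 rose, 2 fell and 2 did not pass (adjusted over the list alone, 12 and 2, camera higher, adjusted p = 1.27e-09). MMP9 rose 3.32-fold. The remaining genes fixed in advance that passed had log2 fold changes of 1.83 ± 0.17 for CCL20, 0.89 ± 0.17 for CXCL8 and 1.93 ± 0.14 for CXCL1. IL1B also passed, at 0.50 ± 0.06, as did IL23A at 1.75 ± 0.08, S100A7 at 2.01 ± 0.32 and ICAM1 at 0.90 ± 0.09. TNFRSF12A also passed, at 0.15 ± 0.05, as did KRT16 at 0.68 ± 0.20, KRT10 at -0.40 ± 0.09 and FLG at -0.55 ± 0.19. The remaining genes of that set did not pass, with log2 fold changes of -0.11 ± 0.30 for TSLP and 0.16 ± 0.14 for MKI67. Against TNF, leaving out 1 library ended the calls of TNFRSF12A (without TNF 3 and TWEAK with TNF 1 and 3, adjusted p = 0.0544 or more), KRT16 (without TNF 1 and TWEAK with TNF 2, adjusted p = 0.0525 to 0.0756) and FLG (without TNF 1, 2 and 3 and TWEAK with TNF 1 and 2, adjusted p = 0.0538 to 0.140). It moved the log2 fold changes of CXCL6 (without TNF 2, 3.87). The call also ended for FLG with limma-voom (adjusted p = 0.0602).

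Against TWEAK alone, adding TNF changed 10303 genes, 4904 higher and 5399 lower, or 5194 and 5082 with RLE size factors and 4419 and 5926 with upper-quartile scaling. C15orf48 rose 458-fold (8.84 ± 0.21), C3 265-fold (8.05 ± 0.35), TNFAIP2 164-fold (7.36 ± 0.23), CXCL8 156-fold (7.29 ± 0.28) and IL36G 153-fold (7.26 ± 0.20), against log2 fold changes of -4.65 ± 0.31 for ITGA4, -4.49 ± 0.21 for METTL7A and -4.45 ± 0.23 for PADI3. Of 25 cell cycle genes, 0 rose, 25 fell and 0 did not pass (adjusted over the list alone, 0 and 25, camera lower, adjusted p = 1.75e-60). CDC20 had a log2 fold change of -3.02 ± 0.07, beside 13 mitochondrially encoded genes, of which 0 rose, 12 fell and 1 did not pass (adjusted over the list alone, 0 and 12, camera lower, adjusted p = 1.17e-04, adjusted p = 0.227 with an estimated correlation). DEFB4A, with 98 counts against 0, was at least 40.7-fold higher. In this comparison other genes fixed in advance passed, with log2 fold changes of 4.45 ± 0.23 for CCL20, 4.47 ± 0.16 for CXCL1, 1.67 ± 0.06 for IL1B, 1.87 ± 0.08 for IL23A and 4.97 ± 0.16 for CSF3. TSLP also passed, at -0.78 ± 0.27, as did S100A7 at 3.10 ± 0.36, S100A8 at 4.49 ± 0.27, LCN2 at 2.90 ± 0.06 and ICAM1 at 6.13 ± 0.13. TNFRSF12A also passed, at 0.50 ± 0.05, as did KRT10 at 0.23 ± 0.09, FLG at -1.32 ± 0.18, MMP9 at 3.52 ± 0.13 and MKI67 at -2.39 ± 0.14. In this comparison the set's other genes did not pass, with a log2 fold change of -0.04 ± 0.19 for KRT16. Against TWEAK, leaving out 1 library ended the calls of TSLP (without TWEAK 3 and TWEAK with TNF 1, adjusted p = 0.0790 to 0.0900) and KRT10 (without TWEAK 1 and 2 and TWEAK with TNF 1 and 3, adjusted p = 0.0636 to 0.107).

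The interaction of TWEAK with TNF asks whether the combination differs from the product of the separate folds, since the test is on the log2 scale. LY6D, a marker of differentiating keratinocytes, fell with TWEAK and with TNF, to 8.56 and 10.9 CPM from 23.4 CPM, and stood at 61.2 CPM with both (interaction 3.94 ± 0.25). LCN2 did the same, at 46.9 CPM in PBS, 36.5 with TWEAK, 34.6 with TNF and 272 with both (interaction 3.34 ± 0.09). Interactions were also positive for IL36G (3.50 ± 0.65), SPRR2A (3.25 ± 0.38), TNFAIP2 (3.17 ± 0.55) and WFDC5 (3.13 ± 0.22). They were negative for MMP9 (-5.97 ± 0.21), IL32 (-4.14 ± 0.26), SAA1 (-3.47 ± 0.35), ABI3BP (-3.26 ± 0.15) and ESM1 (-3.21 ± 0.25). If the separate increases in CPM are added instead, a value with no test, the expected sum for MMP9 is 4459 CPM against 11490 observed, for SAA1 15.9 against 30.1, and for ESM1 52.2 against 55.5, so these 3 lie below the product and above the sum. IL32, at 59.9 CPM against a sum of 84.9, and ABI3BP, at 9.47 against 53.4, lay below both, while LCN2, at 272 against 24.1, and IL36G, at 27.4 against 1.72, lay above both. The test called 3301 genes, 1233 positive and 2068 negative, so that 37.4% were positive, against 47.4% with RLE size factors and 50.2% with a fit of only the groups compared.

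By list, of 11 antimicrobial proteins and alarmins, 5 were positive, 1 negative and 5 did not pass (adjusted over the list alone, 6 and 1, camera higher, adjusted p = 1.93e-10, adjusted p = 0.0587 with an estimated correlation). Values were S100A8 (2.24 ± 0.44), S100A9 (2.03 ± 0.36) and PI3 (1.09 ± 0.23). Antigen presentation genes numbered 15, of which 0 were positive, 9 negative and 6 did not pass (adjusted over the list alone, 0 and 10, camera lower, adjusted p = 2.58e-05, adjusted p = 0.0587 with an estimated correlation). Values were HLA-B (-0.95 ± 0.07) and PSMB9 (-0.83 ± 0.23). Other cytokines and growth factors had 16 members, and 3 were positive, 7 negative and 6 did not pass (adjusted over the list alone, 4 and 7, camera lower, adjusted p = 2.58e-05, adjusted p = 0.0587 with an estimated correlation). Values were IL23A (-2.30 ± 0.17) and CSF3 (1.94 ± 0.57). Of 18 NF-kB feedback and target genes, 7 were positive, 7 negative and 4 did not pass (adjusted over the list alone, 7 and 7, camera lower, adjusted p = 0.241). Values were NFKB2 (-1.92 ± 0.08), TRAF1 (1.75 ± 0.17) and RELB (-1.61 ± 0.10), the list having a median of 0.02 and a mean of 0.05. Of 13 mitochondrially encoded genes, 9 were positive, 0 negative and 4 did not pass (adjusted over the list alone, 10 and 0, camera higher, adjusted p = 2.58e-05, adjusted p = 0.223 with an estimated correlation). The other genes fixed in advance that passed had interactions of -0.35 ± 0.08 for IL1B and -1.13 ± 0.25 for ICAM1. The others did not pass, with interactions of 0.77 ± 0.50 for CCL20, 1.40 ± 0.56 for CXCL8, 0.47 ± 0.25 for CXCL1, -0.51 ± 0.39 for TSLP and 1.61 ± 0.63 for S100A7. TNFRSF12A did not pass either, at -0.06 ± 0.07, nor did KRT16 at 0.71 ± 0.28, KRT10 at 0.09 ± 0.12, FLG at -0.16 ± 0.24 and MKI67 at 0.40 ± 0.19. Measured against the sum of the CPM increases, with no test, PSMB9, IL23A, IL1B and ICAM1 lay above it. For these interactions, leaving out 1 library ended the calls of PSMB9 (without PBS 1, adjusted p = 0.0549) and CSF3 (without PBS 3, adjusted p = 0.236). It brought a call for S100A7 (without PBS 1 and TWEAK with TNF 1, adjusted p = 0.0134 to 0.0371) and KRT16 (without PBS 1, adjusted p = 0.0177). With the replicate number in the model, CXCL1 (adjusted p = 0.0306) and S100A7 (adjusted p = 0.0353) passed.

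The combination of TWEAK with IL-17A was likewise compared with PBS, with IL-17A and with TWEAK. Against PBS, MMP9 rose 446-fold (8.80 ± 0.18) to 2150 ± 96.4 CPM, CXCL5 439.7-fold (8.78 ± 0.32), CSF3 219-fold (7.77 ± 0.19), SAA1 129.6-fold (7.02 ± 0.22), CXCL3 124-fold (6.95 ± 0.21), IL36G 113-fold (6.82 ± 0.22), PDZK1IP1 112-fold (6.80 ± 0.19) and VNN1 93.0-fold (6.54 ± 0.38). ZP4 had a count ratio of 651 (95% counting interval 116 to 25750) and C15orf48 of 117 (95% counting interval 39.7 to 571). DEFB4A, with 110 counts against 0, was at least 43.4-fold higher. Falls against PBS had log2 fold changes of -4.22 ± 0.11 for CPA4, -3.49 ± 0.16 for ITGA4, -3.41 ± 0.13 for CXCL14 and -2.97 ± 0.20 for ANK1. Of 11 antimicrobial proteins and alarmins, 10 rose, 0 fell and 1 did not pass (adjusted over the list alone, 10 and 0, camera higher, adjusted p = 4.43e-15). S100A8 rose 32.0-fold. NF-kB feedback and target genes numbered 18, and 18 rose, 0 fell and 0 did not pass (adjusted over the list alone, 18 and 0, camera higher, adjusted p = 3.05e-63). BIRC3 rose 28.4-fold. Also among the genes fixed in advance, those that passed had log2 fold changes of 4.33 ± 0.28 for CCL20, 3.08 ± 0.32 for CXCL8, 5.24 ± 0.18 for CXCL1 and 1.89 ± 0.06 for IL1B. IL23A also passed, at 5.52 ± 0.12, as did S100A7 at 3.27 ± 0.36, LCN2 at 2.46 ± 0.06 and ICAM1 at 3.95 ± 0.18. TNFRSF12A also passed, at 0.29 ± 0.05, as did KRT10 at -0.58 ± 0.09, FLG at -1.27 ± 0.16 and MKI67 at -0.36 ± 0.13. The genes of that set short of the threshold had log2 fold changes of 0.45 ± 0.24 for TSLP and -0.24 ± 0.19 for KRT16. In TWEAK with IL-17A against PBS, leaving out 1 library ended the calls of MKI67 (without PBS 1, 2 and 3 and TWEAK with IL-17A 1 and 3, adjusted p = 0.0598 to 0.101). It moved the log2 fold changes of CXCL3 (without PBS 1, 7.61) and S100A7 (without PBS 3, 4.17). The call also ended for MKI67 with no filter (adjusted p = 0.0707).

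Against IL-17A alone, adding TWEAK raised MMP9 54.7-fold (5.77 ± 0.15), from 39.4 ± 7.89 to 2150 ± 96.4 CPM, and BIRC3 13.8-fold (3.78 ± 0.14), and ZP4 had a count ratio of 196 (95% counting interval 66.6 to 951). IL23A rose 5.70-fold and ICAM1 3.76-fold, and of 5 other chemokines, 2 rose, 2 fell and 1 did not pass (adjusted over the list alone, 2 and 3, camera higher, adjusted p = 0.677). CCL5 rose 11.7-fold, while the list's median log2 fold change was -0.41 and its mean 0.33. Of genes that IL-17A had raised, some stood lower with TWEAK present, with log2 fold changes of -2.20 ± 0.23 for C3, -2.02 ± 0.16 for SAA2, -1.85 ± 0.09 for PDZK1IP1 and -0.51 ± 0.06 for LCN2. In all, 2341 genes rose and 1745 fell (57.3% higher). With upper-quartile scaling 1784 rose and 2369 fell (43.0% higher). Of 18 NF-kB feedback and target genes, 11 rose, 0 fell and 7 did not pass (adjusted over the list alone, 12 and 0, camera higher, adjusted p = 3.06e-26). NFKB2 rose 3.03-fold. Of 16 cholesterol synthesis genes, 16 rose, 0 fell and 0 did not pass (adjusted over the list alone, 16 and 0, camera higher, adjusted p = 4.04e-12). Hypoxia and glycolysis genes counted 14, of which 0 rose, 10 fell and 4 did not pass (adjusted over the list alone, 0 and 11, camera lower, adjusted p = 1.09e-08, adjusted p = 0.0903 with an estimated correlation), the carbonic anhydrase CA9 at a log2 fold change of -1.47 ± 0.12. Of 30 interferon-stimulated genes, 4 rose, 11 fell and 15 did not pass (adjusted over the list alone, 4 and 14, camera lower, adjusted p = 0.00835, adjusted p = 0.551 with an estimated correlation), MX2 at -1.05 ± 0.17, and of 11 antimicrobial proteins and alarmins, 0 rose, 2 fell and 9 did not pass (adjusted over the list alone, 0 and 3, camera lower, adjusted p = 0.0118, adjusted p = 0.440 with an estimated correlation). Beside these, genes fixed in advance that passed had log2 fold changes of -0.79 ± 0.21 for CXCL8, 0.72 ± 0.13 for CXCL1, -0.27 ± 0.09 for CSF3 and 0.20 ± 0.05 for TNFRSF12A. Genes fixed in advance that stayed short of the threshold had log2 fold changes of -0.41 ± 0.16 for CCL20, -0.28 ± 0.11 for IL36G, 0.11 ± 0.06 for IL1B, 0.17 ± 0.24 for TSLP and -0.67 ± 0.25 for S100A7. S100A8 did not pass either, at -0.35 ± 0.21, nor did KRT16 at -0.21 ± 0.19, KRT10 at -0.11 ± 0.09, FLG at -0.16 ± 0.17 and MKI67 at 0.07 ± 0.13. Against IL-17A, leaving out 1 library ended the calls of CXCL8 (without IL-17A 3 and TWEAK with IL-17A 1 and 2, adjusted p = 0.0501 to 0.0541), CSF3 (without IL-17A 2 and 3 and TWEAK with IL-17A 2, adjusted p = 0.0869 to 0.123) and TNFRSF12A (without TWEAK with IL-17A 1, adjusted p = 0.0548). It brought a call for CCL20 (without IL-17A 1, adjusted p = 0.0458), IL36G (without TWEAK with IL-17A 1, adjusted p = 0.0237) and S100A7 (without IL-17A 1, adjusted p = 0.0367). It ended the list call of interferon-stimulated genes (without IL-17A 3, camera adjusted p = 0.0688) and antimicrobial proteins and alarmins (without TWEAK with IL-17A 3, camera adjusted p = 0.0527). With the replicate number in the model, S100A7 (adjusted p = 0.0217) passed.

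Against TWEAK alone, adding IL-17A changed 2668 genes, 1433 higher and 1235 lower, or 1346 and 1357 with upper-quartile scaling, and without TWEAK 1 the number was 1748. IL36G rose 77.9-fold (6.28 ± 0.22), CSF3 42.8-fold (5.42 ± 0.15), PDZK1IP1 38.1-fold (5.25 ± 0.16) and SAA2 31.4-fold (4.97 ± 0.35), against log2 fold changes of -2.43 ± 0.11 for CPA4, -1.96 ± 0.15 for GJA5 and -1.73 ± 0.28 for KPRP. Of 11 antimicrobial proteins and alarmins, 10 rose, 0 fell and 1 did not pass (adjusted over the list alone, 10 and 0, camera higher, adjusted p = 8.45e-54). S100A8 rose 17.8-fold, and DEFB4A, with 110 counts against 0, was at least 35.9-fold higher. Of 6 CXCR2-ligand chemokines, 6 rose, 0 fell and 0 did not pass (adjusted over the list alone, 6 and 0, camera higher, adjusted p = 6.90e-81). CXCL6 rose 18.1-fold. Further genes fixed in advance passed here, with log2 fold changes of 3.27 ± 0.25 for CCL20, 3.60 ± 0.36 for CXCL8, 3.77 ± 0.16 for CXCL1, 1.04 ± 0.06 for IL1B and 1.48 ± 0.08 for IL23A. S100A7 also passed, at 2.87 ± 0.36, as did LCN2 at 2.83 ± 0.06, ICAM1 at 1.93 ± 0.14, FLG at -0.88 ± 0.17 and MMP9 at 1.10 ± 0.12. Further genes of the set fell short of the threshold, with log2 fold changes of 0.04 ± 0.24 for TSLP, 0.08 ± 0.05 for TNFRSF12A, -0.22 ± 0.19 for KRT16, -0.09 ± 0.09 for KRT10 and -0.12 ± 0.13 for MKI67.

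The interaction of TWEAK with IL-17A, is again on the log2 scale. SAA1 stood at 3.81 CPM with TWEAK, 59.2 with IL-17A and 18.2 with both (interaction -6.47 ± 0.30). Interactions were also negative for C3 (-4.30 ± 1.01), PDZK1IP1 (-3.40 ± 0.41), VNN1 (-3.19 ± 0.61), SAA2 (-3.08 ± 0.88) and CSF3 (-2.63 ± 0.41). On the scale of added CPM, with no test, the observed level lay below the sum for SAA1 (18.2 against 62.9 CPM), C3 (17.3 against 81.1), PDZK1IP1 (16.6 against 60.0), SAA2 (3.02 against 12.4) and CSF3 (21.3 against 26.2). VNN1, at 3.50 against 2.46, and MMP9, at 2150 against 1038 with an interaction of -1.93 ± 0.21, lay above the sum and below the product. Interactions were positive for DMBT1 (2.64 ± 0.41) and ANK1 (1.93 ± 0.32). The test called 2193 genes, 994 positive and 1199 negative, or 1070 and 1063 without a low-count filter and 868 and 1371 with upper-quartile scaling. Of 30 interferon-stimulated genes, 0 were positive, 17 negative and 13 did not pass (adjusted over the list alone, 0 and 21, camera lower, adjusted p = 6.99e-17, adjusted p = 0.0880 with an estimated correlation). Values were XAF1 (-2.51 ± 0.45) and USP18 (-2.03 ± 0.40). Of 16 matrix remodelling and wound-edge genes, 0 were positive, 8 negative and 8 did not pass (adjusted over the list alone, 0 and 10, camera lower, adjusted p = 2.28e-14). Of 16 other cytokines and growth factors, 1 was positive, 8 negative and 7 did not pass (adjusted over the list alone, 1 and 10, camera lower, adjusted p = 5.16e-08). Values were IL32 (-1.67 ± 0.35) and IL23A (-1.53 ± 0.18), both above the sum of the CPM increases. Of the genes fixed in advance, others that passed had interactions of -1.47 ± 0.46 for CCL20, -0.75 ± 0.08 for IL1B and 0.38 ± 0.12 for KRT10. Others of them did not pass, at interactions of -0.28 ± 0.59 for CXCL8, -0.74 ± 0.25 for CXCL1, -0.82 ± 0.56 for IL36G and -0.23 ± 0.34 for TSLP. S100A7 did not pass either, at -1.07 ± 0.58, nor did S100A8 at -1.19 ± 0.41, LCN2 at -0.14 ± 0.09 and ICAM1 at -0.11 ± 0.27. TNFRSF12A did not pass either, at -0.01 ± 0.07, nor did KRT16 at -0.18 ± 0.27, FLG at 0.23 ± 0.23 and MKI67 at 0.32 ± 0.18. For the interactions named here, leaving out 1 library ended the calls of C3 (without TWEAK 1, adjusted p = 0.0665), SAA2 (without TWEAK 3, adjusted p = 0.170), CCL20 (without PBS 1 and 3, TWEAK 2 and 3, IL-17A 2 and 3 and TWEAK with IL-17A 3, adjusted p = 0.0505 to 0.107) and KRT10 (without PBS 2, TWEAK 1, 2 and 3, IL-17A 1 and 3 and TWEAK with IL-17A 1 and 2, adjusted p = 0.0564 to 0.152). It brought a call for CXCL1 (without TWEAK with IL-17A 3, adjusted p = 0.0404) and S100A7 (without PBS 3, adjusted p = 0.0367). It moved the log2 fold changes of SAA2 (without PBS 2, -3.75) and XAF1 (without PBS 1, -3.20). Calls also ended for C3 with limma-voom (adjusted p = 0.0820), CCL20 with no filter and limma-voom (adjusted p = 0.0548 to 0.0724) and KRT10 with limma-voom (adjusted p = 0.0554). With the replicate number in the model, CXCL1 (adjusted p = 0.00149) and S100A8 (adjusted p = 0.0348) passed.

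TWEAK and TNF were also compared directly, where 9965 genes differed, 5127 higher with TWEAK and 4838 lower, or 5682 and 4332 with upper-quartile scaling. METTL7A, OSBPL7 and PADI3 were 17.3-fold, 11.3-fold and 10.3-fold higher with TWEAK, and the leading differences the other way were log2 fold changes of -6.48 ± 0.37 for C3, -6.40 ± 0.29 for CXCL8, -5.48 ± 0.26 for C1orf68 and -5.31 ± 0.30 for C15orf48. Of 25 cell cycle genes, 25 were higher, 0 lower and 0 did not pass (adjusted over the list alone, 25 and 0, camera higher, adjusted p = 4.32e-65), MKI67 being 5.86-fold higher with TWEAK, and of 13 mitochondrially encoded genes, 11 were higher, 0 lower and 2 did not pass (adjusted over the list alone, 11 and 0, camera higher, adjusted p = 1.54e-08, adjusted p = 0.0688 with an estimated correlation). NF-kB feedback and target genes numbered 18, and 0 were higher, 17 lower and 1 did not pass (adjusted over the list alone, 0 and 17, camera lower, adjusted p = 1.97e-21). IL23A did not pass, with a log2 fold change of -0.13 ± 0.09. Other genes fixed in advance that differed had log2 fold changes of -2.62 ± 0.27 for CCL20, -2.53 ± 0.16 for CXCL1, -3.22 ± 0.32 for IL36G and -1.17 ± 0.06 for IL1B. CSF3 also passed, at -0.68 ± 0.27, as did TSLP at 0.67 ± 0.27, S100A7 at -1.09 ± 0.45, S100A8 at -1.40 ± 0.30 and ICAM1 at -5.23 ± 0.13. TNFRSF12A also passed, at -0.36 ± 0.05, as did KRT16 at 0.72 ± 0.20, KRT10 at -0.62 ± 0.09, FLG at 0.77 ± 0.17 and MMP9 at -1.79 ± 0.12. For those that did not pass, the log2 fold change was 0.08 ± 0.07 for LCN2. DEFB4A was at or under the floor in both groups. Between TWEAK and TNF, leaving out 1 library ended the calls of CSF3 (without TWEAK 2 and TNF 1 and 2, adjusted p = 0.0735 to 0.167), TSLP (without TWEAK 1 and 3 and TNF 2 and 3, adjusted p = 0.0672 to 0.162) and S100A7 (without TWEAK 1, 2 and 3 and TNF 2 and 3, adjusted p = 0.0793 to 0.178). Calls also ended for CSF3 with no filter, limma-voom and a fit of only the groups compared (adjusted p = 0.0620 to 0.0879) and S100A7 with limma-voom (adjusted p = 0.117).

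Between TWEAK and IL-17A, 4073 genes differed, 2307 higher with TWEAK (56.6%) and 1766 lower, against 1843 and 2275 (44.8%) with upper-quartile scaling. MMP9 was 25.5-fold (4.67 ± 0.14) and BIRC3 6.34-fold (2.66 ± 0.14) higher with TWEAK, and ZP4 had a count ratio of 132 (95% counting interval 44.9 to 645). The other way, log2 fold changes were -7.10 ± 0.15 for PDZK1IP1, -6.99 ± 0.29 for SAA2, -6.62 ± 0.36 for C3 and -6.56 ± 0.21 for IL36G, and DEFB4A, with 0 counts against 262, was at least 80.1-fold lower. Of 11 antimicrobial proteins and alarmins, 0 were higher, 10 lower and 1 did not pass (adjusted over the list alone, 0 and 11, camera lower, adjusted p = 1.89e-48). Of 6 CXCR2-ligand chemokines, 0 were higher, 6 lower and 0 did not pass (adjusted over the list alone, 0 and 6, camera lower, adjusted p = 1.15e-24). Other genes fixed in advance with a difference that passed had log2 fold changes of -3.69 ± 0.24 for CCL20, -4.39 ± 0.33 for CXCL8, -3.05 ± 0.16 for CXCL1, -0.93 ± 0.06 for IL1B and 1.03 ± 0.10 for IL23A. CSF3 also passed, at -5.69 ± 0.15, as did S100A7 at -3.53 ± 0.34, S100A8 at -4.50 ± 0.27, LCN2 at -3.34 ± 0.07 and FLG at 0.72 ± 0.16. Without a difference that passed, log2 fold changes were 0.13 ± 0.24 for TSLP, -0.01 ± 0.17 for ICAM1 and 0.12 ± 0.05 for TNFRSF12A. KRT16 did not pass either, at 0.01 ± 0.19, nor did KRT10 at -0.02 ± 0.09 and MKI67 at 0.19 ± 0.13.

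The responses to the single cytokines were set against each other across the 17598 genes, which are not independent replicates. Against PBS, 3504 genes changed in the same direction with TWEAK and with TNF, 2121 higher and 1383 lower, where independent lists would share 961 and 663, and 691 changed in opposite directions. For TWEAK and IL-17A, 3390 changed in the same direction, 1967 higher and 1423 lower (independent lists, 602 and 395), and 178 in opposite directions. For IL-17A and TNF, 3572 changed in the same direction, 2001 higher and 1571 lower (independent lists, 1028 and 884), and 1144 in opposite directions. Simulated values are means over 20 simulations of groups without any effect against the same PBS libraries. Between the log2 fold changes of TWEAK and TNF, Pearson's r was 0.529 (simulated 0.458), Spearman's rho 0.423, and the covariance 0.277 (simulated 0.0212). Between TWEAK and IL-17A, Pearson's r was 0.604 (simulated 0.473), Spearman's rho 0.607, and the covariance 0.193 (simulated 0.0210). Between IL-17A and TNF, Pearson's r was 0.459 (simulated 0.466), Spearman's rho 0.358, and the covariance 0.281 (simulated 0.0213). Simulated r, from groups without effect, is no baseline here. The simulated covariances argue against shared controls as the main source of those observed. Part of the shared calls and of r may come from these controls. MMP9, CXCL5, SAA1 and IL23A rose in each of the 3 comparisons with PBS, while LCN2 fell with TWEAK and with TNF and rose with IL-17A.

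The effect of TWEAK alone was set beside its effect in the presence of TNF or IL-17A, comparisons that share no libraries and were chosen after the values had been seen. Beside TNF, 2529 genes were called in both with the same direction, 1510 higher and 1019 lower (independent lists, 501 and 388), and 323 in opposite directions (independent lists, 899), with r = 0.406 and rho = 0.387 across genes. Beside IL-17A, 2219 genes kept their direction, 1421 higher and 798 lower (independent lists, 419 and 226), and 186 turned (independent lists, 616), with r = 0.478 and rho = 0.377.

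On GRCh38, in the GENCODE 29 annotation matched by gene ID, MMP9 is ENSG00000100985.7, chromosome 20, 46008908 to 46016561.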

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

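The tests of scaling on the cell cycle genes, transcript length, neighbouring genes and paralogs below were set before their results were seen, and those of scaling on the antimicrobial genes, mixed wells, NFKBIZ, ZP3 and regrouped libraries were chosen after.

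The effect of TWEAK differed between cells with and without TNF for 3301 genes, and between cells with and without IL-17A for 2193, by edgeR's interaction tests. LY6D and LCN2 were among the first and SAA1 and C3 among the second, with the values given above. Regrouping the libraries 100 times, the true grouping included, called as many genes as the true grouping in 3 cases with TNF (true count 3047 in this test) and in 2 with IL-17A (true count 2406). The highest other count with TNF, 10620, set all libraries with TNF against the rest. The highest with IL-17A, 5102, set all with TWEAK against the rest, so these reflect the effect of 1 cytokine alone. Another 89 groupings with TNF and 97 with IL-17A called no gene, but mixed treatments widen their spread, so this cannot judge chance.

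For the 11 comparisons of 2 groups, 6 libraries give only 10 groupings, too few to judge chance. In each, 1 grouping, the true one, reached the true count (6107 for TWEAK against PBS, 10047 for TNF against PBS, 6298 for IL-17A against PBS, 10718 for TWEAK with TNF against PBS, 7201 for TWEAK with IL-17A against PBS, 5170 for TWEAK with TNF against TNF, 3967 for TWEAK with IL-17A against IL-17A, 10215 for TWEAK with TNF against TWEAK, 3150 for TWEAK with IL-17A against TWEAK, 10208 for TWEAK against TNF and 5338 for TWEAK against IL-17A), and the highest other count was 0.

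The first pattern is the rise of antimicrobial genes such as LCN2 and S100A8 with TWEAK and TNF beyond the product of the separate folds. Of 11 list members, 5 were positive, 1 negative and 5 did not pass, and the list call ended with an estimated correlation (adjusted p = 0.0587). RNA from IL-17A wells could do this, but the 5 positive members as a set would need 89.9% IL-17A RNA, or an impossible 121.6% RNA from TWEAK with IL-17A. At these shares 12 of 50 genes and 16 of 121 (13.2%) would lie higher than they do, against a 10% bound. MKI67 stood at 46.7 CPM, against 215 with IL-17A. This argues against mixing as the whole cause. Smaller shares were not tested. Scaling does not remove the pattern: the lower median interaction of all 11 members under RLE and upper-quartile scaling was 1.907, against 1.885 with TMM. NFKBIZ, a regulator of such genes, had an interaction of 1.002 (adjusted p = 3.87e-07 by edgeR), as a part in the rise would require, but no test tells whether it acts on them.

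The next pattern is the rise of ZP4, an oocyte gene, with TWEAK and TNF. The 1 tested gene within 500 kb, AL359924.1, an antisense gene that overlaps ZP4, had a log2 fold change of 4.702 with TWEAK and TNF, so reads of a transcript across both could be counted as ZP4. It stood at 0.540 CPM against 60.7 CPM for ZP4, and since the strandedness is not stated, this remains open. Among the paralogs ZP1, ZP2 and ZP3, the highest stood at 13.3% of ZP4, over the bound of 10% set for shared reads. That paralog, ZP3, did not follow ZP4 with TWEAK or TNF alone (log2 fold change plus 2 SE at most 0.311), though it rose with both (0.94 ± 0.13, adjusted p = 1.24e-07 by edgeR).

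The last pattern is the fall of the cell cycle genes, MKI67 and TOP2A among them, with TNF. Scaling could lower a whole list, but the higher list median under RLE and upper-quartile scaling was -2.459. A trend of the fold change over exon length could do so too, but with that trend taken out the median was -2.418. A lower share of dividing cells might account for the fall, and counting cells would test it.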

How the results depend on the processing

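The counts of genes stayed within 1.5 times the values above with RLE size factors, upper-quartile scaling, either other filter, DESeq2, limma-voom and a fit of only the groups compared. They fell with a fold threshold of 1.5 in the test, to 507 for TWEAK against PBS, 3698 for TNF against PBS, 757 for IL-17A against PBS, 4699 for TWEAK with TNF against PBS, 1385 for TWEAK with IL-17A against PBS, 645 for TWEAK with TNF against TNF, 297 for TWEAK with IL-17A against IL-17A, 3256 for TWEAK with TNF against TWEAK, 168 for TWEAK with IL-17A against TWEAK, 2815 for TWEAK against TNF, 374 for TWEAK against IL-17A, 250 for the TNF interaction and 72 for the IL-17A interaction. At an adjusted p under 0.01 the counts that moved by more than 1.5 times were 2701 for TWEAK with IL-17A against IL-17A, 1548 for TWEAK with IL-17A against TWEAK, 2650 for TWEAK against IL-17A, 1920 for the TNF interaction and 1098 for the IL-17A interaction. Both follow from asking more of each gene. Leaving out 1 library gave 1748 to 2728 genes for TWEAK with IL-17A against TWEAK, the lowest without TWEAK 1, and the other counts stayed within 1.5 times. The shared calls of TWEAK, TNF and IL-17A against PBS stayed within 1.5 times under each alternative tried. Of 351 pairs of list and comparison camera called 198, or 100 with an estimated correlation. The mixed test of fry, for change in either direction, called 317. Of the called pairs, 6 were lost with fry's directional test, 5 without a filter and 0 with RLE size factors. Refits that left out 1 library, mostly outside the comparison, lost the call of a pair 55 times and kept it 3509 times, which overstates stability.

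Each of the 440 results for a named gene in a comparison was redone, 373 of them called. Calls were lost for 7 with limma-voom, 4 without a filter and 4 with a fit of only the groups compared, each given beside its result. No called gene changed direction under these settings. Genes that did not pass changed sign near 0, with log2 values of 0.003 for KRT16 in TWEAK against PBS and 0.034 for ICAM1 in TWEAK against IL-17A with limma-voom, 0.003 for TNFRSF12A in the IL-17A interaction with no low-count filter, 0.006 for TNFRSF12A in the IL-17A interaction and -0.004 for KRT16 in TWEAK against IL-17A with a fit of only the groups compared, -0.001 for KRT16 in TWEAK against IL-17A with RLE size factors, 0 for KRT16 in TWEAK against IL-17A with DESeq2. With 1 library left out the following, which did not pass, changed sign: in TWEAK against PBS S100A7 -0.013 to 1.304 and KRT16 -0.216 to 0.145, in IL-17A against PBS KRT16 -0.229 to 0.132, in TWEAK with TNF against PBS KRT16 -0.258 to 0.103, in TWEAK with TNF against TNF TSLP -0.348 to 0.103 and MKI67 -0.032 to 0.257, in TWEAK with TNF against TWEAK KRT16 -0.099 to 0.026, in the TNF interaction KRT10 -0.021 to 0.170 and FLG -0.431 to 0.005, in TWEAK with IL-17A against IL-17A MKI67 -0.055 to 0.132, in TWEAK with IL-17A against TWEAK TSLP -0.097 to 0.181 and KRT10 -0.185 to 0.010, in the IL-17A interaction CXCL8 -0.542 to 0.009, ICAM1 -0.280 to 0.171, TNFRSF12A -0.050 to 0.039 and KRT16 -0.351 to 0.010, in TWEAK against IL-17A TSLP -0.005 to 0.345, ICAM1 -0.178 to 0.273, KRT16 -0.055 to 0.106 and KRT10 -0.045 to 0.013. The cause was not tested. Measured against the sum of the separate increases in CPM, a value with no test, called negative interactions became positive log2 ratios, in the TNF interaction 1.366 for MMP9, 0.919 for SAA1, 0.089 for ESM1, 0.262 for PSMB9, 0.851 for IL23A, 0.239 for IL1B and 0.872 for ICAM1 and in the IL-17A interaction 0.509 for VNN1, 1.051 for MMP9, 0.149 for IL32 and 0.960 for IL23A, which follows from the scale.

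With the replicate block, the replicate number in the model, counts moved by less than 1.5 times, for example to 3612 for the TNF interaction and 2525 for the IL-17A interaction, 7 results of 4 named genes gained a call, given above, and none lost it. The call of matrix remodelling and wound-edge genes in TWEAK with IL-17A against IL-17A was lost (camera adjusted p = 0.0963). The numbers are not said to pair wells. Of 45 pairs of libraries with the same number, 20 had deviations from their group means that correlated above 0.1 (12086 genes, -0.211 to 0.359, median 0.085, against -0.02 for different numbers), and 13 of 18 libraries correlated best with their own number. Depth limits genes near the floor of 3 counts over a group, such as DEFB4A, for which only bounds or wide intervals can be given.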

Other observations

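Some genes moved against both cytokines when TWEAK and TNF were combined, a pattern sought after the values had been seen, with the genes named here chosen after their values were seen. By edgeR's test, 15 genes fell with TWEAK and with TNF and rose with both, a course that makes the interaction positive by itself. Besides LY6D and LCN2 they include NDRG2, which had log2 fold changes of -0.55 ± 0.09 with TWEAK, -1.05 ± 0.10 with TNF and 0.79 ± 0.09 with both, and the cytochrome CYP2S1, with -0.62 ± 0.13, -0.71 ± 0.14 and 0.51 ± 0.13. The opposite course was taken by 4 genes, MAP7D3, NETO1, NTNG1 and PSG5, the last with 0.73 ± 0.10, 0.26 ± 0.10 and -0.49 ± 0.11. With TNF, leaving out 1 library ended the calls of PSG5 (without PBS 1 and 2 and TNF 2 and 3, adjusted p = 0.0614 to 0.237). The call also ended for PSG5 with no filter and a fit of only the groups compared (adjusted p = 0.0693 to 0.0842).

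For other genes, also chosen after their values were seen, the effect of TWEAK turned with the company it kept. SAA1 rose with TWEAK alone (4.77 ± 0.29 on the log2 scale) and fell when TWEAK was added to IL-17A (-1.70 ± 0.10), and the bacterial sensor gene NOD2 did so too (0.96 ± 0.24 and -1.42 ± 0.18). KCTD4 rose with TWEAK alone (1.58 ± 0.24) and fell when TWEAK was added to TNF (-1.33 ± 0.22), while ACKR3, a scavenger receptor of chemokines, fell with TWEAK alone (-1.52 ± 0.26) and rose on top of TNF (1.05 ± 0.33). Against TNF, leaving out 1 library ended the calls of ACKR3 (without TNF 2 and TWEAK with TNF 1, adjusted p = 0.0563 to 0.0724).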
